A study of Caenorhabditis elegans with 2 samples.

How the data were processed

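Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole hermaphrodite Caenorhabditis elegans larvae of the first stage (L1), 6 hours after synchronization from starved L1, per the labels. The worms carried an integrated transgene that expresses ZTF-11, a zinc-finger transcription factor of the MYT1 family, fused to GFP. Chromatin was sheared by sonication and immunoprecipitated with an antibody against GFP. The labels give 1 group with 2 biological replicates, so no comparison between conditions was made and no p-value measures spread between animals.

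The deposited files are 8 lists of regions: each replicate alone, both replicates pooled, and a list kept by an irreproducible discovery rate (IDR) threshold, each on 2 genome builds, ce10 and ce11. Per the text files deposited with the samples, each list was called on the replicate's or the pooled alignments with a control alignment, and the authors derived the IDR list from the replicate and pooled lists. The caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The peak signal in the authors' lists is the caller's own value on a scale that differs between lists, so it was mainly used to rank or describe regions within a list. Between lists, signals were compared by rank across the replicates and at equal rank across the builds. The deposited −log10 of the q-value was capped within each list and was not used beyond its range. Summit offsets in the authors' lists gave the position of each summit. Read depth is unknown from these lists, and the control library was not analysed here.

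Positions are on ce11 (WBcel235), counted from 1. Genes came from Ensembl annotation of WBcel235, with 19973 protein-coding genes on the nuclear chromosomes, and sequence from the RefSeq copy of the same assembly. No coordinate was converted between builds. A gene was counted as having a peak where an IDR summit lay within 1000 bp of its annotated 5' end, so a summit between divergent genes counted for both. For genes whose transcripts are trans-spliced, the annotated 5' end can lie downstream of the start of transcription. Regions of the pooled list ranked after 18750 by signal served as background.

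Peaks of 2 lists were matched where summits lay within 100 bp, and chance was taken from 1000 circular shifts of the peaks within each chromosome. The share of peaks near 5' ends and the class of each summit were tested with 10000 such shifts, two-sided, and the smallest p-values these can give are 0.001 and 0.0001. Gene lists written before the data were examined were tested against all other protein-coding genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 26 lists and a call at an adjusted p under 0.05. Odds ratios had 0.5 added to each cell and have normal-approximation 95% intervals on the log scale. For 13 motifs, windows of 50 bp either side of the summit were compared with windows centred 400 bp to each side by the exact McNemar test, adjusted over motifs, and a call needed both sides; the larger adjusted p is printed. The same test was run for every 6-mer with reverse complements merged, with a summit-to-flank ratio over 1.5 required. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

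The text names the coding gene nearest to each of the 25 peaks of highest signal, ztf-11, unc-119, up to 6 members of each list with a peak and up to 3 without, and any member of the MuvB and corepressor lists, by a rule fixed before the data were examined. Alternatives fixed at the same time were other distances (500 and 2000 bp, or the single nearest gene), other matching rules, windows of 25 and 100 bp, the 937 peaks of highest signal, other backgrounds (for motifs, 1875 background regions drawn at random), and the top list of either replicate alone. The single nearest gene had no limit of distance. Windows with the same number of G and C bases, drawn within 1000 bp of coding 5' ends that had no peak within 2000 bp, were added after the motif and 6-mer shares had been seen, and were compared by Fisher's exact test. They were not matched for the class of sequence, such as coding exon or intergenic. The circular-shift test of gene lists uses the ratio of the list's share to that of other genes; this form replaced a first one with a pseudocount after its values had been seen, because that form gave lists with no peak the smallest possible p.

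The statistics were tested on simulated data. With random peaks the promoter share was called in 0 of 20 sets and any gene list in 1 of 20. With planted peaks both were called in 20 of 20. The simulated lists held genes drawn at random, and the random peaks were placed evenly. Real lists whose members lie in clusters or share peaks were not simulated, so the 1 of 20 need not hold for them. Of 1875 simulated peaks 70.0% were planted as matched and 70.0% were recovered. No 6-mer of 2080 was called in random windows, and a planted 6-mer was. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1 were used.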

Results

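ZTF-11 binding was mapped in 2 biological replicates of L1 larvae. The IDR list held 1875 peaks on ce11, and each replicate list and the pooled list held 30000 regions that include background. Every IDR peak was found in the pooled list with the same signal, and the lowest-ranked one was at rank 1875, so the IDR list is the top of the pooled list. Read depth is unknown here, so the precision of single peaks rests on the 2 replicates.

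Most of the strongest sites were found in both replicates. Of the 1875 strongest regions of replicate 1, 1291 (68.9%, 95% interval 66.7 to 70.9) had a match among the 1875 strongest of replicate 2, against a mean of 0.398% after circular shifts (permutation p = 0.001, the smallest possible). Of the 1875 IDR peaks, 1642 (87.6%, 85.99 to 89.03) had a match among the 1875 strongest regions of replicate 1 and 1492 (79.6%, 77.7 to 81.4) among those of replicate 2. Both replicates matched 1298 IDR peaks (69.2%, 67.1 to 71.3), but these peaks were ranked on both replicates pooled, so this share is not independent of either replicate. In the full lists 95.1% of IDR peaks were matched in both replicates, against 2.64% of 11250 background regions. Across the 1783 IDR peaks matched in both full lists, Spearman's rho of the 2 signals was 0.71. Peaks are not independent replicates and were picked partly on these signals, so rho has no p.

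**Figure D1:**
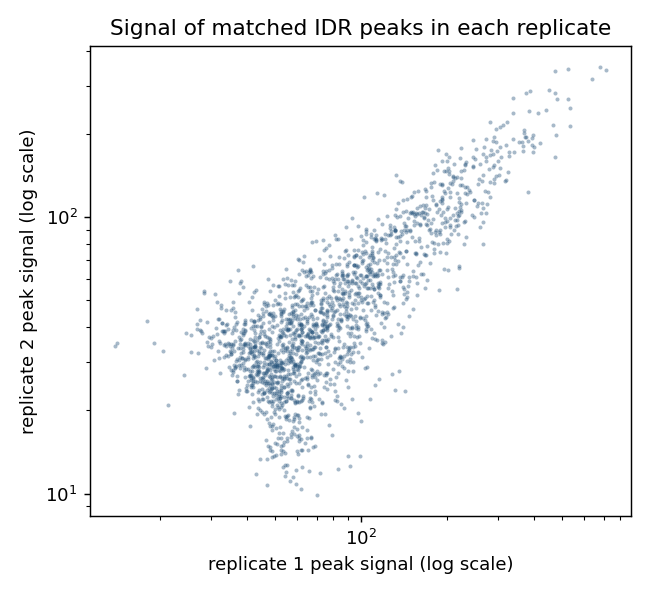
Signal of each IDR peak matched in both replicates (points, n = 1783), replicate 1 on the horizontal and replicate 2 on the vertical axis, both log scales in the caller's units. The signals rose together, with a Spearman's rho of 0.71 across peaks.

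The 25 peaks of highest signal lay mostly in intergenic sequence close to coding 5' ends. Of these peaks, 21 had a coding 5' end within 1000 bp, 19 summits were intergenic, and all 25 were matched in both replicates, ranked 64 or better in replicate 2 and 37 or better in replicate 1. The first was on chromosome III from 7520729 to 7520979, 1 bp upstream of the 5' end of cux-7 (WBGene00000854), with a pooled signal of 1072 and ranks 1 and 3 in the replicates. The second, on chromosome I from 11374324 to 11374580, lay 124 bp upstream of F56G4.6 (signal 1024), and the third, on chromosome III from 11946428 to 11946667, had its summit in an intron 473 bp downstream of the 5' end of Y56A3A.7 (signal 954). Among the others were ribosomal protein genes: rpl-3 (rank 4, signal 885, chromosome III, 3867453 to 3867693), rpl-15 (rank 9, 752, chromosome IV, 654822 to 655041) and rpl-35 (rank 15, 671, chromosome III, 7854586 to 7854804). The rest lay at egg-5 (rank 5, signal 804), C47E8.4 (rank 6, 794), tasp-1 (rank 8, 756), W04C9.4, Y17G9B.5, F25H9.7, T07F10.3, his-68, tag-340, Y50D4C.5, Y22D7AL.10, lrpr-1, egl-30 (a Gq alpha subunit), K10D2.5 and F10E9.5. The peak assigned to egg-5 was 23 bp from the 5' end of the spliced-leader RNA gene sls-2.4, and that of tag-340 was 36 bp from the non-coding RNA gene F26F4.14. The 4 peaks without a coding 5' end in range started at 14055096 and 1151376 on chromosome V, 12612528 on chromosome III and 4209147 on chromosome X.

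ZTF-11 peaks were concentrated at the 5' ends of genes and were rare in coding sequence. Summits lay within 1000 bp of a coding 5' end for 1183 peaks (63.1%, 60.9 to 65.3), against 34.2% ± 1.16 (SD over 10000 circular shifts; permutation p = 0.0001, the smallest possible). Among background regions the share was 35.5%. It was 75.2% (71.0 to 79.1) in the 468 peaks of highest signal and 54.6% (49.95 to 59.2) in the 469 of lowest. The median distance from a summit to the nearest coding 5' end was 444 bp. Intergenic sequence held 64.1% of summits against 32.7% after shifts, introns 17.2% against 34.8%, and coding exons 2.35% against 24.7%. Exons of non-coding genes or pseudogenes held 11.7% against 2.94%, and 5' UTRs 3.52% against 1.42%. For each class, 3' UTRs (1.12% against 3.40%) included, the adjusted permutation p was 0.0001, the smallest possible.

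Chromosomes I and III carried the most ZTF-11 peaks for their gene number, and V the fewest. Chromosome III had 366 peaks, 1.48 times the number expected from its coding genes, I had 361 (1.34 times), X 324 (1.26 times), II 302 (0.933 times), IV 266 (0.864 times) and V 256 (0.546 times). The share of coding genes with a peak at the 5' end was 13.4% on III, 12.02% on I, 7.92% on II, 6.89% on IV (6.05 to 7.81), 6.22% on X (5.35 to 7.20) and 4.95% on V (4.36 to 5.58). Genes on X had a peak less often than autosomal genes pooled, though the share on V was lower than that on X: 170 of 2731 (6.22%) against 1445 of 17242 (8.38%), an odds ratio of 0.727 (0.617 to 0.857; Fisher's exact p = 8.4e-05). Genes in the central part of each chromosome, between 1/3 and 2/3 of its length, had a peak slightly more often than those outside it (8.63% against 7.76%, odds ratio 1.12, Fisher's exact p = 0.030). That small difference was not past the threshold with a distance of 500 bp (odds ratio 1.07) or in the 937 strongest peaks (1.09).

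In all, 1615 of 19973 coding genes (8.09%) had a peak at the 5' end; 966 did with the 937 strongest peaks. Of 26 gene lists, 9 had more members with a peak than other genes and 3 had fewer. The highest shares were in the MuvB and Rb list, whose products repress cell-cycle and germline genes, and in ribosomal proteins. Fisher's test takes genes that share a peak as independent. By circular shifts the adjusted permutation p was 0.0013 for ribosomal proteins. It was 0.0026 for mitochondrial respiration genes and for corepressor and chromatin regulators. For the whole MuvB and Rb list, called MuvB for short below, it was 0.011, for core histones 0.022 and for cell cycle genes 0.029. Pan-neuronal, heterochronic and Wnt genes were not past the threshold by these shifts.

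Ribosomal protein genes had a peak at 47 of 79 members (59.5%, 47.9 to 70.4; odds ratio 17.1, Fisher's exact adjusted p = 3.2e-30), among them rpl-3, rpl-15, rpl-20, rpl-35, rpl-27 and rps-1, and not rpl-2, rpl-11.1 or rpl-39. The peaks counted for rpl-20 and rpl-27 were those nearest to Y17G9B.5 and egl-30. Mitochondrial respiration genes had 16 of 37 (43.2%, 27.1 to 60.5; odds ratio 8.80, Fisher's exact adjusted p = 6.7e-08), led by cox-5A (signal 524) and atp-1 (252), subunits of cytochrome c oxidase and ATP synthase. Core histones had 22 of 72 (30.6%, 20.2 to 42.5; odds ratio 5.12, Fisher's exact adjusted p = 1.8e-07), with 1 peak shared by his-67 and his-68 (signal 674) and 1 by his-31 and his-32 (493). Histone genes are near-identical copies in clusters, and reads shared between copies make their peaks uncertain.

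Genes of the MuvB and Rb list and of the list of corepressor and chromatin regulators had peaks at their 5' ends more often than other genes. In the MuvB and Rb list 8 of 13 members (61.5%, 31.6 to 86.1; odds ratio 17.6, Fisher's exact adjusted p = 6.9e-06) had a peak. These were lin-54 (signal 449), lin-35, the retinoblastoma homolog (381), lin-53 (311), lin-9 (303), lin-36 (173), efl-1 (149), lin-13 (97.5) and lin-15B (71.8). The members efl-2, dpl-1, lin-37, lin-52 and hpl-2 had none. The lin-54 peak was on chromosome IV from 13240591 to 13240806, 344 bp upstream of the 5' end, and the lin-35 peak on chromosome I from 5807453 to 5807628, 196 bp upstream. The lin-35 peak was also counted for another coding gene. With only genes that have no other coding 5' end within 2000 bp the odds ratio was 15.4, with a peak at 2 of 5 such members, and was not past the threshold. Corepressor and chromatin regulators had 14 of 32 (43.8%, 26.4 to 62.3; odds ratio 8.98, Fisher's exact adjusted p = 2.9e-07). Among these were mrg-1 (signal 344), set-2 (271), an H3K4 methyltransferase, rcor-1 (212), a CoREST homolog, and unc-37 (94.5), a Groucho homolog. The histone deacetylase genes hda-1, hda-2 and hda-3 had none, nor had sin-3, let-418, ctbp-1, hpl-1, hpl-2, met-2, spr-1 or spr-5. Both lists hold lin-53, lin-13 and hpl-2, so their calls are not independent. The lin-61 peak (signal 109) had no match within 100 bp in replicate 2 and also served bub-1.

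Cell cycle, pan-neuronal, heterochronic and Wnt genes also had more peaks, with odds ratios under 5 and calls that some settings removed. Cell cycle and replication genes had 13 of 45 (28.9%, 16.4 to 44.3; odds ratio 4.75, Fisher's exact adjusted p = 0.00012), led by hcp-6 (signal 370) and pcn-1 (360), the sliding clamp of replication; cdk-1, cdk-2 and cyd-1 had none. Pan-neuronal genes had 9 of 32 (28.1%, 13.7 to 46.7; odds ratio 4.61, Fisher's exact adjusted p = 0.0021), including syd-2 (154), unc-108 (141), ehs-1 (123), unc-76 (120), tba-1 (84.6) and ric-19 (81.8), of which unc-108 (a Rab GTPase) and tba-1 (an alpha tubulin) act in many tissues. The synaptic genes rab-3 and snb-1 had none. Heterochronic genes had 5 of 18 (27.8%, 9.69 to 53.5; odds ratio 4.64, Fisher's exact adjusted p = 0.026), among them lin-28 (200) and nhl-2, whose peak is that of tag-340. The summit of the tag-340 peak was 36 bp from the 5' end of the non-coding RNA gene F26F4.14. There were also peaks at 7 of 30 Wnt pathway genes (23.3%, 9.93 to 42.3; odds ratio 3.64, Fisher's exact adjusted p = 0.021), among them wrm-1 (280) and mig-5 (270). Calls were lost for pan-neuronal genes without replicate 2 (odds ratio 2.86), for heterochronic and Wnt genes at 500 bp (1.26 and 1.87), for pan-neuronal, cell cycle and Wnt genes with the 937 strongest peaks (3.11, 3.25 and 2.51), and for pan-neuronal, heterochronic and Wnt genes with circular shifts in place of Fisher's test. They were also lost for Wnt and heterochronic genes with named genes as background (2.75 and 3.51), and for heterochronic genes among those with no other coding 5' end within 2000 bp (6.58).

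The gene given to a peak, and the distance allowed, changed the size of these differences. With the single nearest gene of each peak all 9 lists stayed called, with lower odds ratios for ribosomal proteins (25 of 79, odds ratio 5.28), core histones (13 of 72, 2.54), mitochondrial respiration genes (12 of 37, 5.500) and MuvB genes (6 of 13, 9.70). They were higher for pan-neuronal genes (18 of 32, odds ratio 14.4), heterochronic genes (9 of 18, 11.2) and Wnt genes (12 of 30, 7.58). This rule has no limit of distance, and 25.4% of summits lay beyond 2000 bp of a coding 5' end. Genes were not matched for the space around them, so these higher values need not mean more peaks close to 5' ends. Among genes with no other coding 5' end within 2000 bp the odds ratios were 31.5 for ribosomal proteins, 40.5 for mitochondrial respiration, 14.1 for cell cycle and 7.64 for Wnt genes.

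Chemoreceptor, nuclear hormone receptor and neuropeptide genes had fewer peaks than other genes. Chemoreceptor families had 7 of 1364 (0.513%, 0.207 to 1.05; odds ratio 0.0584, Fisher's exact adjusted p = 8.7e-40), nuclear hormone receptors 5 of 269 (1.86%; odds ratio 0.234, adjusted p = 8.3e-05) and FMRFamide-like and neuropeptide-like genes 1 of 102 (0.980%; odds ratio 0.167, adjusted p = 0.0080), the 1 being nlp-4 (signal 439). The summit counted for nlp-4 lay 77 bp upstream of the 5' end of the snoRNA gene F59C6.15. The receptor genes with a peak included srh-16, sri-5, nhr-142 and nhr-47. With circular shifts in place of Fisher's test, the call held for chemoreceptors but not for nuclear hormone receptors or neuropeptides. The shift test can hardly call fewer peaks in small lists. Even lists of 23 to 36 genes with no peak at all had an adjusted permutation p of 0.61 to 0.76. How far this limits the larger lists of 102 and 269 genes was not tested. The neuropeptide call was also lost at 500 bp, with the 937 strongest peaks, with the single nearest gene and among genes with no other coding 5' end within 2000 bp, and the nuclear hormone receptor call in the last of these. Over all settings but the circular shifts odds ratios were 0.0350 to 0.0962 for chemoreceptors, 0.155 (without replicate 1) to 0.386 for nuclear hormone receptors and 0.126 to 0.391 for neuropeptides (0.296 without replicate 1). Collagens had 5 of 156 (3.21%; odds ratio 0.410, Fisher's exact adjusted p = 0.051), which were col-71, col-38, col-185, col-2 and col-85. They were called lower without replicate 1 (odds ratio 0.271), at 2000 bp (0.405) and with named genes as background (0.308).

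The lists of neurogenesis, of neuron class identity and of tissues other than the nervous system as a whole were not called. No peak was found at any of 34 neuronal terminal selectors (such as unc-86 and unc-3), 36 neurotransmitter and sensory identity genes (such as unc-17 and cha-1), 36 epidermis and seam genes (such as elt-1 and elt-3) or 23 glia genes (such as mls-2); the exact intervals reach 10.3%, 9.74%, 9.74% and 14.8%, above the 8.09% of all coding genes, so a lower share was not detectable in any 1 of them. Neurogenesis regulators had 2 of 25, lin-32 (signal 137), a proneural gene, and pig-1 (109), with none at hlh-2, hlh-3 or hlh-4. With the single nearest gene of each peak, neurogenesis regulators and Notch genes each had 5 of 25 (odds ratio 2.998, 1.17 to 7.69), terminal selectors 3 of 34 (1.24) and glia genes 2 of 23 (1.297), and these lists were not called either. Muscle genes had 2 of 37 (unc-60 and act-4), intestine 1 of 37 (erm-1), pharynx 1 of 30 (lin-35) and germline 1 of 43 (spo-11, with a peak shared with swsn-4). Notch genes had 2 of 25 (adm-4 and sel-10), Hox and cofactor genes 2 of 12 (ceh-20 and mab-5; 4 of 12 with the single nearest gene, odds ratio 5.92, which was called), ceh homeobox genes 2 of 63 (ceh-38 and ceh-20) and hlh genes 2 of 25 (hlh-11 and hlh-30).

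**Figure D2:**
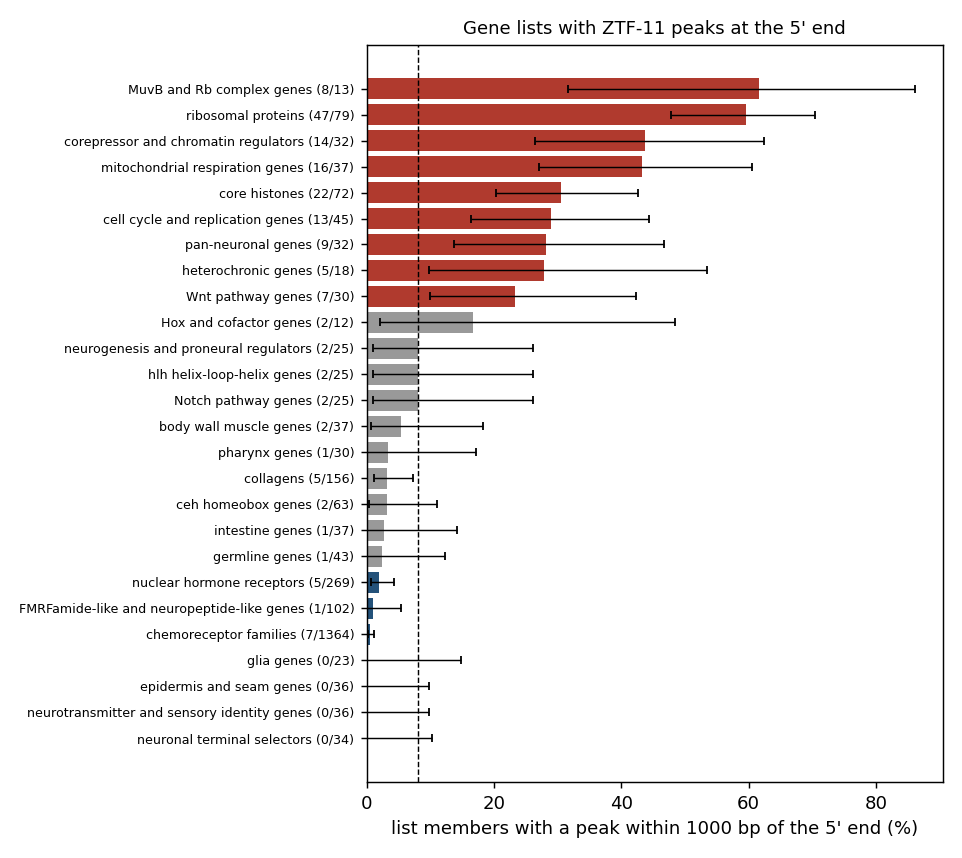
Share of each list's members with an IDR summit within 1000 bp of the 5' end (bars, percent; whiskers, exact 95% intervals; counts beside the names); red lists were called higher, blue lower and grey not called. The dashed line is the 8.09% of all coding genes; MuvB and ribosomal protein lists exceed 59%.

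The AAGTT core known for MYT1-family proteins was less frequent at ZTF-11 summits than beside them, and other sequences were more frequent. AAGTT was within 50 bp of 13.2% of summits against 33.3% of flank windows (ratio 0.397, exact McNemar adjusted p = 4.1e-45), and 31.7% of the 11250 background summits. GAGAGA was at 23.8% against 6.00% (ratio 3.97, exact McNemar adjusted p = 7.0e-49), CTGCGTCT at 8.75% against 0.400% (ratio 21.9, adjusted p = 4.3e-39) and GGCGGG at 7.73% against 2.03% (ratio 3.82, adjusted p = 2.4e-14). The CHR element TTYGAA, known for MuvB, was at 21.8% against 30.8% (ratio 0.708, exact McNemar adjusted p = 6.3e-10). In a split that was not planned, TTYGAA was not called in the 1183 peaks within 1000 bp of a coding 5' end (25.7% against 29.0%, ratio 0.885) or in the 468 of highest signal (0.876), and its ratio was 0.448 in the 692 farther peaks. GGCGGG was called within that distance (ratio 5.45) and not farther away (2.00), while AAGTT (0.491 and 0.254), GAGAGA (3.81 and 4.18) and CTGCGTCT (31.7 and 15.3) were called in both sets. The differences between the 2 sets were not tested. Summit windows held 48.9% ± 7.87 (SD over windows) G and C, against 36.3% and 35.7% in the flanks and 35.4% in the genome.

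Windows with the same number of G and C bases near coding 5' ends without a peak gave another order for some motifs, in a comparison added after these shares had been seen. AAGTT stayed lower at summits (13.2% against 23.7%, ratio 0.559, Fisher's exact adjusted p = 6.6e-16), and GAGAGA (ratio 2.76), CTGCGTCT (7.45) and GGCGGG (1.63) stayed higher. TTYGAA turned from lower to higher (21.8% against 14.1%, ratio 1.55, Fisher's exact adjusted p = 2.6e-09), as did TTTGAA (ratio 1.498), TAATTA (2.74) and TTTTTTT (1.35). CACGTG (flank ratio 2.85), CANNTG (1.36), WGATAR (0.587) and AAAGTTT (0.312) were past the threshold against flanks and not against matched windows. TGACTCA was not called (0.907% against 0.667%).

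Of 2080 6-mers, 602 were more frequent at summits, 462 of them with at least 4 G or C bases. The highest ratios were those of GCGCGC (10.8% of summits, ratio 15.6), CGCGCG (7.79%, 15.4) and ACGCGC (13.8%, 10.6). Against the windows matched for G and C content 294 were called, 230 of them also called against flanks, and GCGCGC again had the highest ratio (4.95).

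**Figure D3:**
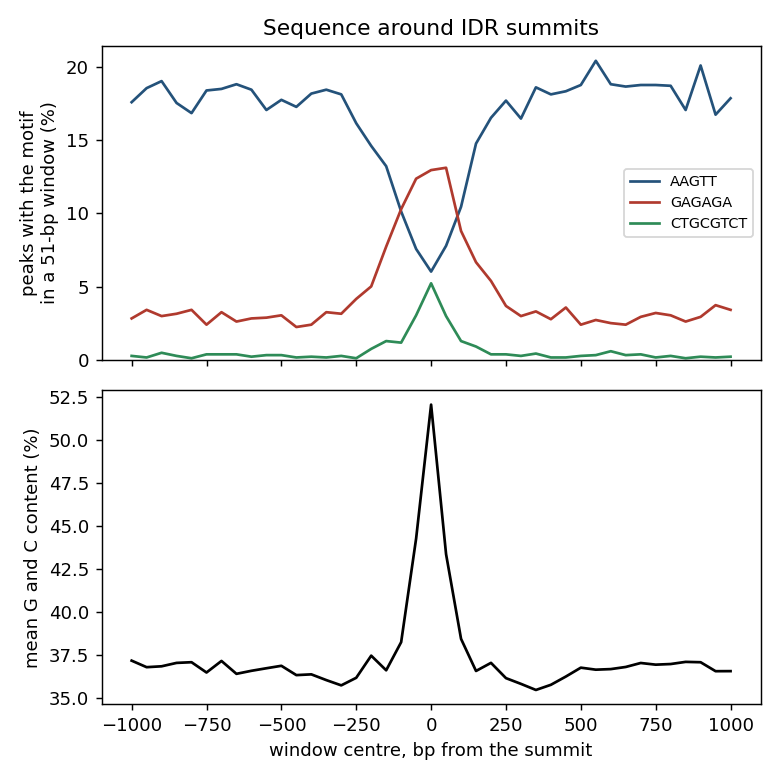
Percent of IDR peaks with AAGTT, GAGAGA or CTGCGTCT in windows of 51 bp (upper panel) and mean G and C content in percent (lower panel, axis not from 0), against the distance of the window from the summit in bp. AAGTT dips at the summit while GAGAGA, CTGCGTCT and G and C content peak there.

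The tagged gene itself had peaks. At ztf-11 (WBGene00009939, chromosome I, 9904303 to 9910545, minus strand) a peak from 9910580 to 9910943 lay 217 bp upstream of the 5' end (signal 81.2) and another from 9908865 to 9909228 was in an intron (130). Within 20 kb of the gene's midpoint 6 IDR peaks were found, against a median of 0 over coding genes, the strongest from 9918169 to 9918389 (356) and from 9904144 to 9904255 (252). The marker gene unc-119 (chromosome III, 10902641 to 10908935) had no peak at its 5' end. The strain carries a ztf-11 transgene, so signal here can come from the transgene as well as the native locus.

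**Figure D4:**
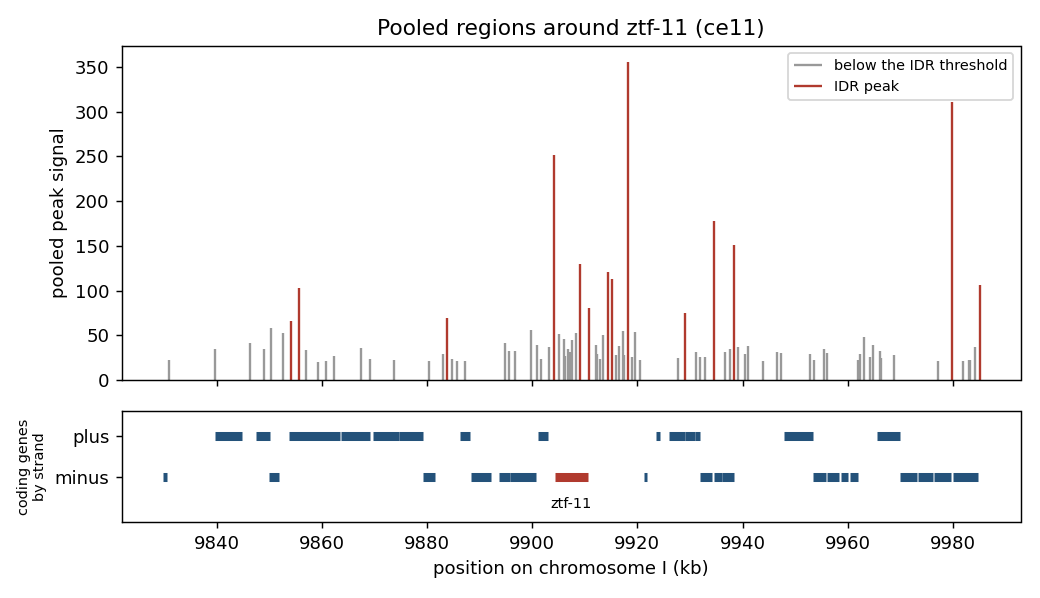
Pooled regions around ztf-11 on chromosome I (upper panel; height, pooled peak signal; red, IDR peaks; grey, regions below the IDR threshold) and coding genes by strand (lower panel), against position in kb on ce11. Within 20 kb of the ztf-11 midpoint lie 6 IDR peaks and 25 regions below the threshold.

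The 2 genome builds gave nearly the same list. The IDR list held 1882 peaks on ce10 and 1875 on ce11, with summed widths of 632777 and 630241 bp and a median width of 364 bp on both. At equal rank the signals differed by a median of 0.000284% and at most by 0.985%. The pooled list had a median signal of 27.5 on both builds, and replicate 1 a median of 18.5 and replicate 2 of 12.8.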

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

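The tests of base composition, G and C content, ztf-11, unc-119 and gene density were chosen after the results had been seen; windows of 100 bp, the single nearest gene and genes without a close neighbour had been chosen before, but were read as tests of an explanation only afterwards.

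Regions of the pooled list below the IDR threshold, which no comparison of the report uses as peaks, were dense around ztf-11: 25 lay within 20 kb of the gene's midpoint, against a median of 11 over coding genes, and 99.5% of coding genes had fewer. Among genes with a like number of coding 5' ends in the window 99.4% had fewer, which argues against gene density as the source. A candidate explanation is extra copies of the region in the transgenic strain, which would raise signal along the whole copied stretch. The marker gene unc-119, with 23 such regions in a window of the same 40 kb, also exceeded 98.7% of genes, though only 94.1% by the list of replicate 2 alone. How much of either window the transgene holds is not known here, so the unc-119 count does not decide on extra copies. Binding of ZTF-11 to its own locus stays open, since the transgene and the native locus cannot be separated in these lists and the control library was not analysed here. No biological explanation was tested.

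AAGTT was less frequent at summits than in flanks. Base composition does not account for it alone: against windows with the same number of G and C bases the ratio was 0.559. Summits displaced by up to 100 bp would give more AAGTT in wider windows, but with 100 bp either side the ratio was 0.481. Contact through other sequences or other proteins may give this pattern and was not tested, and matching on G and C content leaves the order of bases unmatched. The class of sequence was not matched either, while 2.35% of summits lay in coding exons and 64.1% in intergenic sequence. A difference between coding and other sequence therefore stays open. No biological explanation was tested, since the design has 1 group.

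Of the gene lists, 9 had more peaks than other genes. All 9 kept odds ratios above 1 by their 95% intervals within 10 strata of the G and C content of their 5' ends (3.43 to 21.6). Content within 250 bp of the 5' end is thus not the whole cause. The median summit lay 444 bp from the nearest coding 5' end, so these strata cannot decide on the content at the summits. Among genes with no other coding 5' end within 2000 bp, 6 of these lists were still called. This argues against peaks counted for a neighbouring coding gene as the whole cause there. Neighbouring non-coding genes were not removed, so peaks that belong to them were not tested. Of the peaks at tRNA, snoRNA and snRNA genes, 30, 26 and 9 also had a coding 5' end within 1000 bp. The odds ratio of ribosomal proteins was 17.1 over all genes, 31.5 (9.43 to 105) among genes without a close coding neighbour and 5.28 with the single nearest gene of each peak. For 2 lists the call ended while the odds ratio did not fall to 1, MuvB (17.6, 6.03 to 51.6, against 15.4, 3.04 to 78.4) and heterochronic genes (4.64, 1.72 to 12.5, against 6.58, 1.98 to 21.9), because only 5 and 14 members were left; this lost call is no evidence for neighbouring genes, and core histones could not be tested. Whether other tagged proteins would be recovered at the same 5' ends in these larvae was not analysed here and stays open.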

How the results depend on the processing

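Windows matched for G and C content, and the form of the statistic in the circular shifts of gene lists, were chosen after the data had been seen; the other alternatives were planned. Among results that answer a comparison, 212 values under alternatives kept their direction and side of the threshold, or stayed within 1.5 times for counts, while 26 were no longer past the threshold, 4 reversed and 4 counts moved further. The share of IDR peaks matched in both replicates was 64.7% to 87.8% over all alternatives, and the share at 5' ends 52.1% to 74.6%, above the shifts in each. The excess in central parts of chromosomes was not past the threshold at 500 bp (1.07) or with the 937 strongest peaks (1.09), and that stricter list, which holds fewer peaks, gave 966 genes. Of the lists with fewer peaks, 1 stayed called among genes with no other 5' end within 2000 bp and 1 with circular shifts. No longer past the threshold, by odds ratio, were at 500 bp Wnt (1.87), heterochronic (1.26) and neuropeptide genes (0.216); with the stricter list pan-neuronal (3.11), cell cycle (3.25), Wnt (2.51) and neuropeptide genes (0.289); with named genes as background Wnt (2.75) and heterochronic (3.51); with the single nearest gene neuropeptide genes (0.391); and among genes with no other 5' end in range MuvB (15.4), heterochronic (6.58), neuropeptide (0.143) and nuclear hormone receptor genes (0.386), where fewer genes were tested and core histones had too few to test. With circular shifts the same held for pan-neuronal (3.35), heterochronic (3.30), Wnt (2.505), neuropeptide (0.122) and nuclear hormone receptor genes (0.279). Values given for shifts here and below are the ratio of shares divided by its mean after shifts. Leaving out a replicate gave pan-neuronal genes odds ratios from 2.86 to 4.16. Lists not called became called in 4 cases, Hox genes with the nearest gene (5.92) and collagens, lower, at 2000 bp (0.405), with named genes (0.308) and without replicate 1 (0.271, against 0.4997 without replicate 2). Others had printed values on the other side of 1, which the 0.5 added to each cell can cause in lists with few peaks. With named genes and with shifts these were neurogenesis regulators (0.913 and 0.918), Notch genes (0.913 and 0.932) and hlh genes (0.913 and 0.964). The hlh genes were also at 0.864 at 2000 bp and at 0.731 to 1.24 without a replicate. In the main setting each of these lists had an odds ratio of 1.21, but a ratio of shares of 0.989. Their values under 1 are therefore no change of direction in the shares. With the nearest gene, terminal selectors (1.24) and glia genes (1.297) crossed 1. Muscle genes did so at 500 bp (1.03), without close neighbours (1.06) and without a replicate (0.840 to 1.97). So did intestine genes without close neighbours (1.501), pharynx genes without a replicate (0.607 to 1.02) and Hox genes at 500 bp (0.586). Against windows matched for G and C content, TTTGAA (1.498), TTYGAA (1.55), TTTTTTT (1.35) and TAATTA (2.74) reversed, AAAGTTT (0.894), CANNTG (1.08), CACGTG (1.22) and WGATAR (0.963) were no longer past the threshold, and 294 6-mers were called. TGACTCA, not called, fell below 1 with the stricter list (0.571), background peaks (0.773), matched windows (0.739) and either replicate left out (0.914 to 0.929). Beyond the smaller sets named, the cause was not tested. Read depth is unknown from these lists, so its part in these limits was not assessed.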

Other observations

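The gene types, name classes and genes named in this part were chosen after the data had been seen. ZTF-11 summits were frequent at snoRNA, tRNA and snRNA genes and rare at piRNA genes. A summit lay within 100 bp of the 5' end of 62 of 346 snoRNA genes (17.9%, against 0.420% after 1000 circular shifts), 86 of 612 tRNA genes (14.1% against 0.385%) and 16 of 129 snRNA genes (12.4% against 0.356%), each with a permutation p of 0.001, the smallest possible (adjusted 0.0020). At piRNA genes there were fewer than after shifts, 7 of 15363 (0.0456% against 0.306%, ratio 0.149, with the same p). Of the 83 peaks at tRNA genes, 53 had no coding 5' end within 1000 bp. Median signals were 90.7 for peaks at tRNA genes (107.8 for other peaks), 106 at snoRNA genes (107) and 297 at the 15 peaks of snRNA genes (107). The last included the spliced-leader RNA genes sls-2.4 (signal 804), sls-2.1 (518) and sls-2.2 (349). Of 261 miRNA genes, 4 had a summit in that range (adjusted permutation p = 0.037). Genes of several of these types occur in near-identical copies, so reads shared between copies make single assignments uncertain.

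Of 175 classes of coding genes that share a name stem, 20 had a peak more often than other genes and 13 less often (Fisher's exact test, adjusted over classes). Beside the ribosomal, histone and lin classes, the higher ones included eif translation initiation factors (9 of 25, odds ratio 6.57), vps vacuolar sorting genes (10 of 31, 5.58), sec secretion genes (8 of 19, 8.44), hsp heat shock genes (8 of 22, 6.69) and taf genes of the TFIID complex (7 of 17, 8.15). The peaks counted for hsp-90 (pooled rank 6) and hsp-60 (rank 19) are those nearest to C47E8.4 and Y22D7AL.10, and eif-3.B had a peak at rank 59. The peak counted for vps-51 (rank 94) is the one also counted for lin-35. For sec-15 (rank 449) the summit lay 78 bp upstream of the 5' end of a tRNA gene. These classes are therefore not independent of the lin class and of the tRNA result. The lower ones included clec C-type lectin genes (4 of 240, odds ratio 0.214) and fbxa F-box genes (3 of 170, 0.236).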
